A study of Mus musculus with 10 samples.

How the data were processed

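Droplet-based single-cell RNA sequencing was read from 10 libraries of mouse pancreatic islets, 1 library per group. Per the labels' protocols, mice had food ad libitum (AL) or were fasted intermittently (IF), in cycles of 24 h without food and 48 h with food, for 9 to 10 weeks or for 4 to 5 weeks, and were killed 48 h after the last cycle. The groups were middle-aged AL and IF (MAL, MIF), old AL and IF (OAL, OIF), young AL and IF over the long schedule (YAL, YIF), young AL and IF over the short schedule (YAL_short, YIF_short), young mice before the schedule (Ybaseline) and a young group named YIF_AL, whose order and length of feeding are not given in the sources used here. The number of animals per library is not given either, so a library was taken as 1 sample whatever it pooled. The 6 young libraries were made with kit version 2 and sequenced on another instrument than the 4 older libraries, made with kit version 3.1, so kit and age class cannot be told apart.

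Values were deposited as raw UMI counts per gene and barcode. The lowest total of a deposited barcode was 500 UMIs in the older libraries and between 5067 and 6075 UMIs in the young ones, so the young files hold no barcodes of low depth. Per the submitters' processing notes, Cell Ranger 2.1.1 and 3.1.0 and the mouse build GRCm38 (mm10) were used. Which library went with which version is not given in the sources used here. The young files list 31125 genes and the older files 31253, and genes were joined by their Ensembl IDs. The protocol's aim was 50000 reads per cell. Positions were taken from the GENCODE annotation (mouse release 21, GRCm build 38), in which 14703 of the 14709 genes tested in β-like cells had their ID, as did 86 of 86 named genes.

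Cells were kept with at least 1000 UMIs, 500 detected genes and at most 15% mitochondrial UMIs. Barcodes above the mitochondrial limit numbered 1328 in MAL, 1108 in MIF, 1032 in OAL and 1503 in OIF, against 13 to 48 in the young libraries. Doublets were scored with Scrublet per library, and the highest scores were removed at 0.8% per 1000 barcodes, so the number removed follows from that rate. Cells were clustered per kit (scanpy 1.11.5, leidenalg 0.10.2) on 2000 variable genes, 30 principal components, 15 neighbours and resolution 1. Hormone genes, the β maturity and immaturity lists, and mitochondrial, ribosomal and sex check genes were left out of the clustering. A cluster took the name of a class from fixed markers, of which at least 3 had to be detected in 25% of its cells, and the name carries "-like". The rules on clusters of mixed identity were settled after the clusters had been seen and before any comparison of expression: at most 20% scored doublets in the cluster, at most 40% insulin UMIs outside β, leading genes taken from those of at least 50 CPM and detected in 10% of cells, and no second hormone in the median cell above 20% of its level in its own class. These rules left cells unnamed, amounting to 5.51% of MAL, 6.93% of MIF, 3.19% of OAL, 6.17% of OIF, 7.22% of YAL, 3.82% of YIF, 3.03% of YAL_short, 3.32% of YIF_short, 5.17% of YIF_AL and 3.73% of Ybaseline.

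Cells were not treated as replicates. Counts were summed per library and class, and the sums were tested with edgeR 4.0.16 (quasi-likelihood test, TMM factors, filterByExpr, Benjamini-Hochberg threshold 0.05) in R 4.3.3. An IF and an AL library of the same age and duration made a pair, and the 4 pairs served as the replicates of the IF effect. One fit had a term per pair and 1 IF term, with 3 residual degrees of freedom. Another had separate IF terms for young and older mice, which gave the effects in the 2 young pairs, in the 2 older pairs, and the difference between them. Its 2 residual degrees of freedom were shared by both age classes. A gene's own spread there came from the disagreement of the 2 young pairs and from that of the 2 older pairs. edgeR moderated it toward a trend shared across genes, with 6.40 prior degrees of freedom against these 2. In the fits over 4 pairs the prior had 5.24 in β-like, 13.6 in α-like and 14.3 in δ-like cells, against 3 residual ones. In each of these fits the trend across genes thus weighed more than the gene's own spread. Old was compared with middle-aged over MAL, MIF, OAL and OIF, and long with short over YAL, YIF, YAL_short and YIF_short, each with diet as a term and 1 residual degree of freedom. Old against middle-aged had 5.69 prior degrees of freedom. An edgeR p-value measures the spread between these libraries, moderated by the prior, and this spread may be technical. Shares of cells were compared by an exact two-sided sign-flip permutation test over the 4 pairs, whose smallest p is 0.13, and each share has an exact 95% binomial interval. Values of a single pair have no test: both libraries are given in TMM-scaled CPM with exact 95% Poisson intervals, and log2 ratios were taken with 0.5 counts added. These intervals cover counting error only.

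The 18 gene lists were β maturity, β immaturity, genes disallowed in β cells, exocytosis and excitability, oxidative phosphorylation, glycolysis, unfolded protein response, integrated stress response, dissociation and immediate early, proliferation, fasting with FoxO and PPAR targets, autophagy and lysosome, cholesterol synthesis, senescence, interferon and antigen presentation, α identity, acinar enzymes, and a sex check. Of 413 entries, 409 matched a gene of the files. Entries left unmatched were Ero1b, Tmem27, Amy2b and Spink3. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation and with fry. At the preset value camera sets the gene statistics of a list against those of the other genes. Members that move together count there as nearly independent. Its p-value thus does not measure the spread between libraries and may be too small. With an estimated correlation, camera takes its degrees of freedom from the 1 to 3 residual ones of the fits. Few lists can pass there, so a list that does not pass is neither upheld nor refuted. For single pairs, the percentile of a list's median was taken among 10000 random lists of the same size drawn within 20 bins of expression. The samples, designs, gene lists, markers, naming rule and most alternatives were fixed before the data were examined.

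The naming rule took genes past the threshold with a mean of at least 20 CPM and the same sign in every pair of the contrast, the 10 highest and the 10 lowest log2 fold changes. For single pairs it took genes of at least 100 CPM in either library, 10 each way in the young long pair and 5 each way in the others. Mitochondrial, ribosomal and haemoglobin genes, numbered gene models, sex check genes, acinar enzymes and markers of other classes were left out of that rule. A set of 12 genes of β-cell function was to be always named, and 2 to 4 members were named per list described. Of these 12, 2 are not reported here, nor is 1 gene of the young long pair. For the difference between young and older mice, the same sign in every pair was read as no overlap between the young and the older pairs, and there all genes past the threshold are given.

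Alternatives were DESeq2 1.42.0, relative log expression factors, no low-count filter, hormone genes left out, doublets kept, a stricter cell filter of 2000 UMIs, 1000 genes and 10% mitochondrial UMIs, cells assigned one by one from their hormone UMIs, counts thinned to the lowest library total, no pair term, scaling by library totals, and each pair left out in turn. The assignment of single cells asked for 80% of a cell's scaled hormone UMIs, to which a minimum of 30% of the library maximum was added after the data were seen. Leaving out β-, α- and δ-like cells with a second hormone was also added after the data were seen. The correlations of IF effects between pairs were first computed without haemoglobin genes and then with all genes, as planned. Only the latter are given.

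Each edgeR contrast was run on simulated counts with known changes at folds of 1.5, 2 and 4. The changed genes were drawn from those with a mean of at least 20 CPM, so recovery at lower levels is not covered. The simulated spread was set from the moderated dispersions of the fits and may be smaller than the real one. In the real difference between young and older mice, Mafa, above 20 CPM, differed by more than a fold of 1.5 and did not pass. Recovery in the real libraries may thus be lower than the shares given here. DESeq2, the list tests and the sign-flip test were not run on such counts. In the simulation of the young contrast, over 14709 genes, 100% of the changed genes were recovered at each fold and 40 unchanged genes were called. For the difference between young and older mice, 97.0% were recovered at a fold of 1.5 and 100% at folds of 2 and 4, with 31 unchanged genes called. Over 4 pairs, 100% were recovered at each fold in β-like cells with 22 unchanged genes called, and in α-like cells with 20. In δ-like cells 98.5% were recovered at a fold of 1.5 and 8 unchanged genes were called. The simulations of older mice, of old against middle-aged and of long against short recovered 100% at each fold, with 28, 55 and 12 unchanged genes called. The unchanged genes called outnumbered the real calls for the difference (10), for old against middle-aged (4) and in δ-like cells (3). In α-like cells 20 unchanged genes stood against 23 real calls, and in the young contrast 40 against 120. Real calls in each of these contrasts may be false ones.

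Near-identical copies share reads, so values of Hspa1a and Hspa1b, of Hba-a1 and Hba-a2, of Hbb-bs, and of Tmsb15b2 are uncertain. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, skimage 0.26.0 and matplotlib 3.10.9 were also used.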

Results

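Pancreatic islets of mice that were fasted intermittently (IF) or fed ad libitum (AL) were profiled by droplet-based single-cell RNA sequencing, in 10 libraries with 1 library per group. The series concerns β-cell maturation and function under chronic intermittent fasting in adolescent mice. IF and AL were set against each other in 4 pairs, namely young mice over 9 to 10 weeks (the long pair, YIF and YAL), young mice over 4 to 5 weeks (the short pair), middle-aged mice and old mice. The middle-aged and old libraries are called older below. The files held 4651 barcodes for MAL, 5504 for MIF, 4707 for OAL, 4479 for OIF, 5084 for YIF, 4280 for YIF_AL, 2979 for YAL, 5870 for Ybaseline, 4290 for YIF_short and 4578 for YAL_short. Total UMIs ranged from 81211284 in YAL to 179650507 in MIF, and the median per barcode from 14698 in MAL to 29764.5 in YIF_short.

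Cell classes were named from markers, and β-like cells, which make insulin, were the most frequent class in each library. Between 1452 (OIF) and 3419 (Ybaseline) β-like cells were kept per library. Ins1 and Ins2 together took 34.8% of β-like UMIs in OAL and 63.3% in YAL_short, the lowest and highest of the 10 libraries. Insulin UMIs were also found in endothelial-like cells, where they made up 6.39% to 12.4% of UMIs in the young libraries, 3.96% in MIF, 3.11% in OIF, 0.423% in MAL and 0.3% in OAL. In δ-like cells, 30.4% of the MAL cells, 31.4% of MIF, 32.0% of OAL and 33.3% of OIF also carried a second hormone, against 4.24% to 6.67% in the young libraries.

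The share of β-like cells was higher in the IF library of 3 pairs and lower in that of the old pair. β-like cells were 65.5% of kept cells in YIF and 58.2% in YAL, 63.1% in YIF_short and 55.4% in YAL_short, and 66.5% in MIF and 62.2% in MAL, but 61.4% in OIF and 80.2% in OAL (exact 95% intervals 59.4% to 63.3% and 78.8% to 81.6%). α-like cells, which make glucagon, were 6.09% in OAL and higher in OIF (95% interval 13.6% to 16.5%), and were lower in the IF library of the other pairs, with 16.3% in YIF and 19.8% in YAL. δ-like cells, which make somatostatin, were 8.24% in OIF and 3.22% in OAL, and also lower in the IF library of the other 3 pairs. With single cells assigned by their own hormones, δ-like cells were higher in the IF library of both young pairs (differences in log odds 0.086 and 0.044) and of the old pair. Endothelial-like cells were higher in the IF library of all 4 pairs (mean odds ratio 1.38) and PP-like cells, which make pancreatic polypeptide, were lower in all 4 (mean odds ratio 0.826). The exact sign-flip test over 4 pairs gave p = 0.13 for these 2 classes, the smallest it allows, and an adjusted p of 0.375. For β-, α- and δ-like cells the exact p was 1, and macrophage-like cells were higher in 2 pairs and lower in 2 with an exact p of 0.625. The mean difference in log odds, IF minus AL, of β-, α- and δ-like cells changed sign without the old pair. It went from -0.031 to 0.271 for β, from 0.042 to -0.278 for α and from 0.151 to -0.129 for δ.

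**Figure D1:**
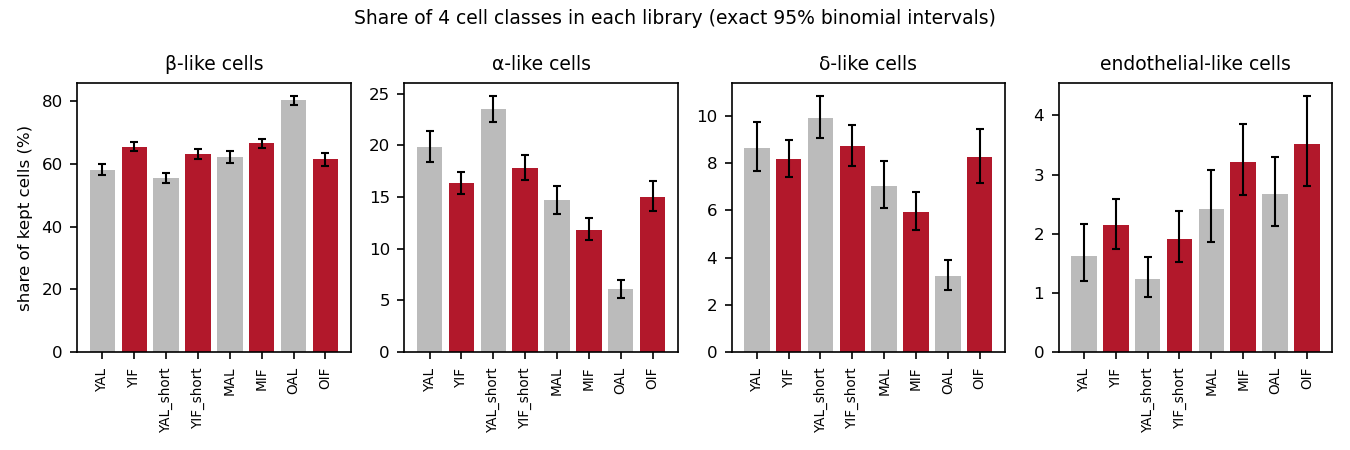
Share of 4 cell classes among kept cells in percent (bars), per library, with exact 95% binomial intervals and the AL library (grey) beside the IF library (red) of each pair. The β-like share was 80.2% in OAL and 61.4% in OIF, while in the other 3 pairs it was higher in the IF library.

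In β-like cells of young mice, genes of the stress response of the endoplasmic reticulum and of amino acid stress were higher under IF, and immediate early genes were lower, in both young pairs. As lists they passed the camera test with a preset correlation and not with an estimated one (adjusted p = 0.552 each). The latter rests on 2 residual degrees of freedom and can call few lists, while the former may give p-values that are too small. Trib3, a pseudokinase induced by stress signalling, rose 2.03-fold (log2 fold change 1.02, SE 0.12, edgeR adjusted p = 0.0197). The effect is that of the 2 young pairs, and the spread that of all 4 pairs, moderated toward the trend shared across genes. Txnip, which inhibits thioredoxin and responds to glucose, fell by 1.08 on the log2 scale (SE 0.11, edgeR adjusted p = 0.0117). Chac1, an enzyme that degrades glutathione, rose by 0.89 (SE 0.08), Herpud1, a membrane protein of endoplasmic reticulum-associated degradation, by 0.78 (SE 0.07), and Dbp, a transcription factor of the circadian output, by 0.92 (SE 0.12), each with an edgeR adjusted p of at most 0.0264. Zfp36, which promotes the decay of AU-rich mRNAs, fell by 1.11 on the log2 scale (SE 0.15), and Rasd1, a small GTPase induced by dexamethasone, by 1.20 (SE 0.19, edgeR adjusted p = 0.0409).

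Of 14709 genes tested in β-like cells of young mice, 60 rose and 60 fell under IF, and 2800 had an unadjusted p under 0.05 (edgeR). The simulation of this contrast called 40 unchanged genes. Of the 120, 53 had a mean of at least 20 CPM, and 52 of these also met the other parts of the naming rule, 28 higher and 24 lower. The other named genes that rose were Ccdc86 (0.88), Srm (0.83), which encodes spermidine synthase, the long noncoding RNA Mir670hg (0.68), Spc25 (0.67), a part of the kinetochore, Tent5a (0.66), a poly(A) polymerase, and Dnajb11 (0.61), a co-chaperone of the endoplasmic reticulum. The other named genes that fell were the immediate early genes Btg2 (-0.96), Jun (-0.87) and Egr1 (-0.82), C2cd4b (-0.87), the transcription factor Irf1 (-0.81), the phosphatase Dusp1 (-0.76) and Socs3 (-0.72), a suppressor of cytokine signalling. Trib3 (ENSMUSG00000032715) lies on chromosome 2 at 152337422 to 152344032 of GRCm38, Chac1 (ENSMUSG00000027313) on chromosome 2 at 119351229 to 119354381, Herpud1 (ENSMUSG00000031770) on chromosome 8 at 94386438 to 94395377, Txnip (ENSMUSG00000038393) on chromosome 3 at 96557957 to 96561883, Dbp (ENSMUSG00000059824) on chromosome 7 at 45705088 to 45710203 and Rasd1 (ENSMUSG00000049892) on chromosome 11 at 59963181 to 59964944. The count of 120 was 3 without the long pair. There the 20 named genes kept their direction, with log2 fold changes of -0.92 to 0.93 against -1.20 to 1.02 with both young pairs, and 0 of them passed. The count was 155 without the short pair, 52 of which were among the 120. It was 1318 without the middle-aged pair and 1313 without the old pair, DESeq2 called 233 genes, and 1158 passed with no low-count filter.

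**Figure D2:**
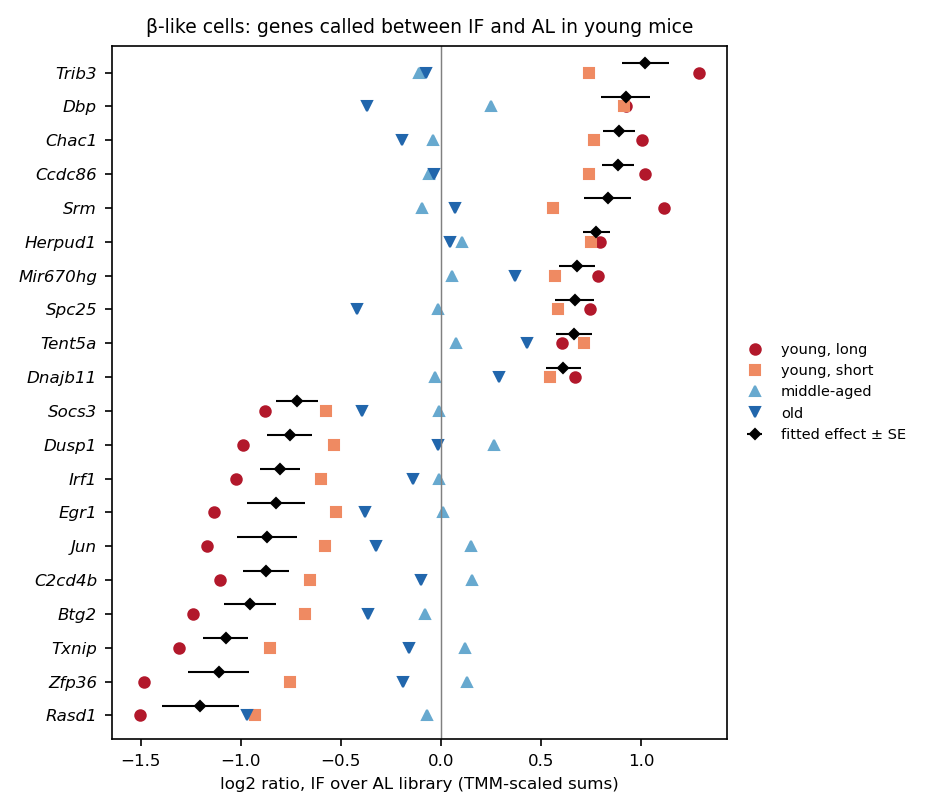
log2 ratio of IF to AL in β-like cells for the genes named in young mice, with a point for each of the 4 pairs and the fitted young effect with its standard error. Trib3 at 1.02 and Rasd1 at -1.20 are the ends of the range of fitted young effects.

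Among the gene lists in β-like cells of young mice, the unfolded protein response rose (camera adjusted p = 2.92e-12, adjusted p = 0.552 with an estimated correlation). Of its 24 members, 23 were higher under IF, 5 rose over all genes tested and 13 when adjusted over the list alone, among them Herpud1, Dnajb11, Atf6 (0.43) and Sel1l (0.39). The integrated stress response, which includes enzymes of amino acid synthesis, rose (camera adjusted p = 2.65e-06, adjusted p = 0.552 with an estimated correlation), with 16 of 20 members higher. Trib3 and Chac1 rose and Ddit4, an inhibitor of growth signalling, fell by 0.46 on the log2 scale, and 12 rose and 1 fell when adjusted over the list alone. The dissociation and immediate early list fell (camera adjusted p = 7.86e-15, adjusted p = 0.552 with an estimated correlation), with 19 of 22 members lower, 7 that fell over all genes tested and 17 that fell when adjusted over the list alone. The cluster with the most β-like cells in YAL was led by Hspa1b, Rasd1, C2cd4b and Txnip and another one was the largest in YIF, so part of these genes also set the clusters apart. YAL itself differed from Ybaseline on these lists, with median log2 ratios of 0.48 for immediate early genes (21 of 22 higher), -0.20 for the unfolded protein response (18 of 24 lower) and -0.23 for the integrated stress response (15 of 20 lower). YIF had -0.30, 0.096 and 0.38 against Ybaseline, as values of single libraries with no test.

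Lists of proliferation, acinar enzymes, maturity and interferon also passed the camera test in β-like cells of young mice. Proliferation was higher in 20 of 22 members with no single gene past the threshold, over all genes or adjusted over the list alone in edgeR (camera adjusted p = 0.000138, adjusted p = 0.552 with an estimated correlation). Acinar enzymes, which β cells do not make, were lower in 20 of 20 members, with 0 past the edgeR threshold over all genes and 15 when adjusted over the list alone (camera adjusted p = 5.83e-08, adjusted p = 0.559 with an estimated correlation). Their summed level in β-like cells was 0.597 CPM in YIF and 13.9 CPM in YAL, and 0.796 CPM in YIF_short and 6.40 CPM in YAL_short. Interferon and antigen presentation was lower in 19 of 27 members, of which 2 fell over all genes and 2 when adjusted over the list alone (camera adjusted p = 0.0175, adjusted p = 0.725 with an estimated correlation). Haemoglobin transcripts of red blood cells summed to 19.3 CPM in YIF and 107 CPM in YAL, and to 28.7 CPM in YIF_short and 252 CPM in YAL_short.

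The β maturity list, which holds insulin genes and the factors of adult β-cell identity, was lower in 18 of 27 members in young IF mice (camera adjusted p = 0.0175, adjusted p = 0.552 with an estimated correlation). Over all genes tested 1 member fell, and 2 rose and 7 fell when adjusted over the list alone. The member that fell was Pdx1, a transcription factor of pancreas development and insulin expression, by 0.41 on the log2 scale (SE 0.07, edgeR adjusted p = 0.0499). Nkx6-1 and Mafa, transcription factors of β-cell identity, had log2 fold changes of -0.35 and -0.26, and G6pc2, the islet glucose-6-phosphatase, 0.36, with edgeR adjusted p of 0.101, 0.175 and 0.0587. Ins1 (-0.10), Ins2 (-0.13), Ucn3 (-0.05), Slc2a2 (-0.08), Slc30a8 (0.04) and Iapp (0.23) did not pass the test (edgeR adjusted p 0.27 to 0.811). The glucose transporter gene Slc2a2, Ins1 and Ucn3, which encodes urocortin 3, took both signs when 1 pair was left out. Against Ybaseline the list median was 0.091 in YAL (17 of 27 higher) and -0.068 in YIF. The cluster that held 36.5% of the β-like cells in YAL and 8.12% in YIF also had Mafa, Ucn3 and Nkx6-1 among its leading genes. Pdx1 (ENSMUSG00000029644) lies on chromosome 5 at 147269959 to 147275848, Mafa (ENSMUSG00000047591) on chromosome 15 at 75745490 to 75748228, and Nkx6-1 (ENSMUSG00000035187) on chromosome 5 at 101658139 to 101664996.

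The other lists did not pass the camera test in β-like cells of young mice. Their adjusted p were 0.711 for α identity, 0.788 for autophagy and lysosome, 0.175 for β immaturity, 0.611 for cholesterol synthesis, 0.918 for genes disallowed in β cells, 0.663 for exocytosis and excitability, 0.175 for fasting with FoxO and PPAR targets, 0.975 for glycolysis, 0.43 for oxidative phosphorylation, 0.611 for senescence and 0.16 for the sex check. In the fasting list, which holds Txnip, 13 of 20 members were lower. For autophagy and for glycolysis the median log2 fold change was positive (0.018 and 0.042) while the test pointed down.

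**Figure D3:**
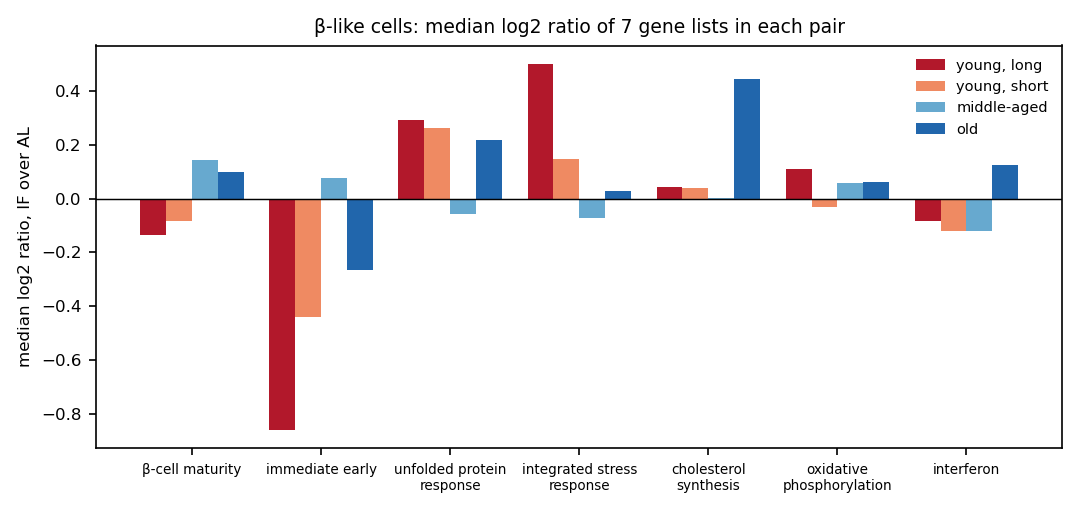
Median log2 ratio of IF to AL of 7 gene lists in β-like cells, with a bar for each of the 4 pairs, as values of single pairs with no test. The immediate early median was -0.86 in the young long pair and 0.08 in the middle-aged pair.

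In β-like cells of older mice no single gene passed the threshold, while lists of cholesterol synthesis, maturity and respiration were higher under IF. Cholesterol synthesis was higher in 21 of 21 members (median 0.22, camera adjusted p = 3.26e-13, adjusted p = 0.55 with an estimated correlation), with Fdps at 0.38 and Insig1 at 0.35. This rested on the old pair (21 of 21 higher, median 0.44), as the middle-aged pair had 11 higher and 10 lower (median 0.0024). The β maturity list was higher in 22 of 27 members (median 0.11, camera adjusted p = 5.06e-06, adjusted p = 0.55 with an estimated correlation). Oxidative phosphorylation was higher in 46 of 58 members (camera adjusted p = 7.76e-05), and the unfolded protein response in 21 of 24 (camera adjusted p = 0.000191). With an estimated correlation the adjusted p of these were 0.55 and 0.577. The unfolded protein response was higher in 22 of 24 members in the old pair and lower in 18 of 24 in the middle-aged pair. The clusters of β-like cells also differed between the old libraries: 1 cluster, with a median mitochondrial share of 7.81% and an insulin share of 30.5%, held 22.1% of the β-like cells in OAL, 9.64% in OIF, 6.70% in MAL and 5.17% in MIF.

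Of 14709 genes tested in β-like cells of older mice, 0 passed with edgeR, which gave 527 an unadjusted p under 0.05, and 0 passed with DESeq2, which gave 172. Mafa had a log2 fold change of 0.35, Ucn3 0.26, Ins1 0.25, Ins2 0.21, Slc2a2 0.20, G6pc2 0.14, Nkx6-1 0.13, Iapp 0.08, Pdx1 0.07 and Slc30a8 -0.03, each with an edgeR adjusted p of 1. α identity (13 of 18 higher, 0.000191), β immaturity (11 of 17, 0.00458), exocytosis (18 of 26, 0.0114), senescence (8 of 13, 0.0362) and autophagy (16 of 20, 0.0401) were also higher by their camera adjusted p. The glucagon transcript Gcg, which β cells do not make, was also found in β-like cells. Without TMM scaling it was at 142 CPM in OAL and 717 CPM in OIF, and at 600 CPM in MAL and 644 CPM in MIF. Acinar enzymes were lower in 18 of 20 (camera adjusted p = 1.15e-06). The acinar genes summed above for young mice had, without TMM scaling, 2.17 CPM in MIF and 27.1 CPM in MAL but 8.23 CPM in OIF and 0.901 CPM in OAL. None of these 6 calls held with an estimated correlation, where the adjusted p was 0.55 to 0.595. Adjusted over the list alone, α identity had 3 members higher and 1 lower, β immaturity 2 higher and senescence 1 higher, against 0 over all genes with edgeR, and the other lists named for older mice had 0 either way. Without the middle-aged pair 440 genes passed, and without the old pair 76. Cholesterol synthesis, autophagy and the unfolded protein response turned direction without the old pair.

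The test of the difference asked whether the IF effect in β-like cells differed between young and older mice, and 10 of 14709 genes passed. In its simulation 31 unchanged genes were called, so these 10 may hold false calls. Chac1 (1.01, SE 0.11, edgeR adjusted p = 0.0283), Ccdc86 (0.93), Pycr1, an enzyme of proline synthesis (0.87), Ciart, a repressor of the circadian clock (1.22), and the linker histone H1f4 (1.15) had a higher IF effect in young mice. Cxcl10, a chemokine induced by interferon (-1.66, edgeR adjusted p = 0.00286), Tifa, an adaptor of innate immune signalling (-1.03), and the haemoglobin genes Hbb-bs, Hba-a1 and Hba-a2 had a lower one. Unadjusted, 1857 genes had a p under 0.05. The log2 difference was -0.62 for Mafa, -0.48 for Pdx1 and -0.48 for Nkx6-1, with edgeR adjusted p of 0.192, 0.192 and 0.224. It was -0.36 for Ins1, -0.34 for Ins2 and -0.30 for Ucn3, and G6pc2 had 0.23, none of which passed.

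By lists, the IF effect in β-like cells was lower in young than in older mice for immediate early genes (20 of 22 members, camera adjusted p = 3.68e-10, adjusted p = 0.643 with an estimated correlation) and for β maturity (20 of 27, camera adjusted p = 2.74e-05, adjusted p = 0.643 with an estimated correlation). Adjusted over the list alone, 14 immediate early genes were lower, and 1 maturity gene was higher and 8 lower, against 0 over all genes with edgeR. It was higher for the integrated stress response (17 of 20 members, camera adjusted p = 4.1e-07) and the unfolded protein response (23 of 24, camera adjusted p = 3.4e-06), each with an adjusted p = 0.69 with an estimated correlation. Of the former 1 member, Chac1, passed over all genes, and 9 were higher and 1 lower adjusted over the list alone, and of the latter 5 were higher adjusted over the list alone. Acinar enzymes and cholesterol synthesis (both 0.00406), β immaturity (0.00553), interferon (0.0189) and α identity (0.0216) were lower by their camera adjusted p, and none of these held with an estimated correlation (0.643 to 0.69). Adjusted over the list alone, interferon had 3 members lower, β immaturity 2 lower and α identity 1 higher and 1 lower. The count of 10 was 4 without the young long pair, 64 without the short pair, 635 without the middle-aged pair and 339 without the old pair. DESeq2 called 49, 508 passed with no low-count filter, 53 when each cell was assigned by its own hormones and 22 without cells that carried a second hormone.

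**Figure D4:**
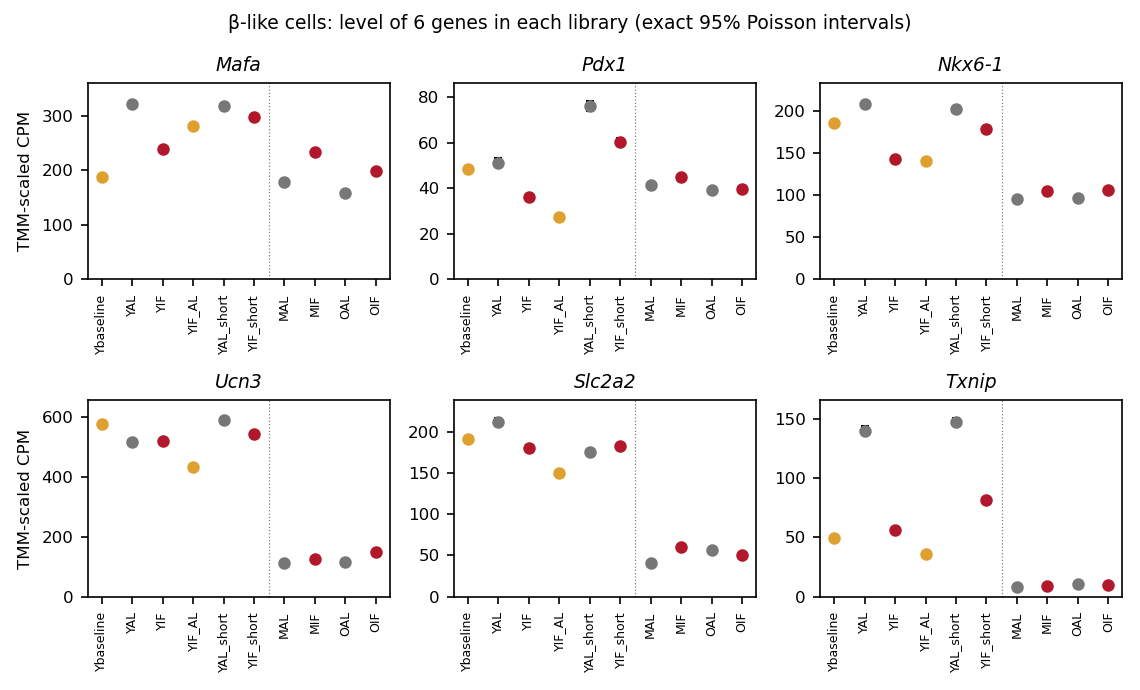
Level of 6 genes in β-like cells in TMM-scaled CPM, with a point per library (AL grey, IF red, YIF_AL and Ybaseline yellow) and exact 95% Poisson intervals that cover counting error only. Mafa was at 239 CPM in YIF, 322 CPM in YAL, 282 CPM in YIF_AL and 188 CPM in Ybaseline.

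In the fit over 4 pairs, the unfolded protein response and cholesterol synthesis were higher and immediate early genes lower in β-like cells under IF, while no single gene passed. The middle-aged pair went the other way on the unfolded protein response (18 of 24 lower, median -0.057), immediate early genes (14 of 22 higher, 0.076) and the integrated stress response (17 of 20 lower). For cholesterol synthesis the median was 0.44 in the old pair and 0.0024 to 0.043 in the other 3. None of the 8 lists called held with an estimated correlation, where the adjusted p was 0.463, or 0.576 for the integrated stress response. The unfolded protein response was higher in 23 of 24 members (camera adjusted p = 2.5e-13), with Herpud1 at 0.42 and Hspa5, the main chaperone of the endoplasmic reticulum, at 0.32. Cholesterol synthesis was higher in 21 of 21 (camera adjusted p = 1.08e-06) and proliferation in 21 of 22 (camera adjusted p = 2.96e-05). Immediate early genes were lower in 20 of 22 (camera adjusted p = 3.06e-12), with 7 that fell when adjusted over the list alone, and acinar enzymes in 19 of 20 (camera adjusted p = 5.16e-15), though in the old pair 19 of these 20 were higher (median 2.88). Oxidative phosphorylation (0.00182), the integrated stress response (0.0287) and senescence (0.036) were higher. Adjusted over the list alone, senescence had 1 member higher and acinar enzymes 2 lower. Of 14709 genes, edgeR called 0 and gave 847 an unadjusted p under 0.05, DESeq2 called 8, and 21 passed in edgeR without the old pair.

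In α-like cells over 4 pairs, immediate early genes fell under IF. Of the 22 members of that list 22 were lower (median -0.52), 11 fell over all genes tested and 19 when adjusted over the list alone (camera adjusted p = 4.09e-46, adjusted p = 0.0205 with an estimated correlation). Gem, a GTPase that restrains calcium channels, fell by 1.18 on the log2 scale (SE 0.14, edgeR adjusted p = 0.00219, lower in 4 of 4 pairs). Atf3 (-0.92), a transcription factor of the stress response, Fosb (-0.72) and Fos (-0.52), partners of Jun, and Zfp36 (-0.57) also fell, with edgeR adjusted p of 0.00928 to 0.0111. Hspa1a, the inducible heat shock protein, and Klf2, a transcription factor, fell by 1.96 and 0.73 on the log2 scale in the fit (edgeR adjusted p = 0.00928 and 0.0146), as members of the list outside the naming rule. Both were lower in the 2 young pairs only, and higher under IF in the middle-aged pair (Hspa1a 0.58, Klf2 0.22) and the old pair (Hspa1a 1.53, Klf2 0.90).

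In α-like cells 1 gene rose and 22 fell of 12345 tested, and 757 had an unadjusted p under 0.05 (edgeR). The simulation called 20 unchanged genes there. The other named genes that fell were Rasd1 (-0.60), Errfi1 (-0.57), an inhibitor of the epidermal growth factor receptor, Dusp1 (-0.54), Junb (-0.52) and Maff (-0.51). Gem (ENSMUSG00000028214) lies on chromosome 4 at 11704457 to 11714752 and Atf3 (ENSMUSG00000026628) on chromosome 1 at 191170296 to 191218039. Cholesterol synthesis was higher in 19 of 21 members (camera adjusted p = 3.31e-10, adjusted p = 0.171 with an estimated correlation), with 0 past the edgeR threshold over all genes and 8 when adjusted over the list alone. The integrated stress response was higher in 14 of 18 (camera adjusted p = 2.29e-05, adjusted p = 0.258 with an estimated correlation) and the unfolded protein response in 20 of 24 (camera adjusted p = 0.000102, adjusted p = 0.269 with an estimated correlation). Senescence (0.0147), fasting (0.0212) and acinar enzymes (3.96e-17) were lower by their camera adjusted p, with an estimated correlation 0.269, 0.447 and 0.269. Adjusted over the list alone, 12 acinar enzymes were lower, and 6 genes of the integrated stress response were higher and 1 lower. With DESeq2 6 of the 10 named genes passed, and without the young short pair 3. The count of 23 was 12 without the young short pair, 43 without the middle-aged pair and 40 without the old pair, DESeq2 called 10, and 147 passed with no low-count filter.

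**Figure D5:**
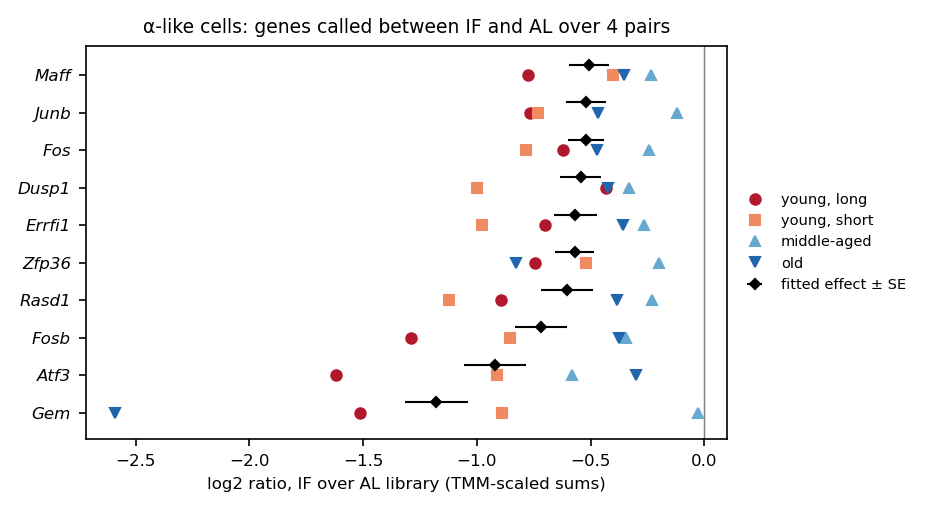
log2 ratio of IF to AL in α-like cells for the named genes, with a point for each of the 4 pairs and the fitted effect with its standard error. Gem at -1.18 had pair values from -2.59 to -0.03.

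In δ-like cells over 4 pairs, 3 of 11912 genes fell and 516 had an unadjusted p under 0.05 (edgeR). The simulation called 8 unchanged genes there. Nupr1, a chromatin protein induced by stress, fell by 0.89 on the log2 scale (SE 0.10, edgeR adjusted p = 0.00113), Gem by 0.64 (edgeR adjusted p = 0.0226) and Nfkbia, an inhibitor of NF-κB, by 0.51 (edgeR adjusted p = 0.0493). Immediate early genes fell as a list, with 21 of 22 lower, 0 past the edgeR threshold over all genes and 17 when adjusted over the list alone (camera adjusted p = 5.91e-35, adjusted p = 0.0146 with an estimated correlation). Acinar enzymes (1.44e-12), fasting, the integrated stress response and interferon (each 0.0109) were lower and the unfolded protein response (0.0037) higher by their camera adjusted p, with an estimated correlation 0.329 to 0.718. Adjusted over the list alone, 7 acinar enzymes and 3 genes of the integrated stress response were lower. The count of 3 was 1 without the young short pair, 20 without the middle-aged pair and 21 without the old pair. DESeq2 called 0, 56 passed with no low-count filter, and 16 without cells that carried a second hormone, which were a larger share of the older than of the young libraries.

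Between old and middle-aged mice, immediate early genes were higher in β-like cells of the old ones. Fosb rose by 0.76 (SE 0.06, edgeR adjusted p = 0.0338), and in its list 17 of 22 members were higher, 1 rose over all genes and 13 rose and 2 fell when adjusted over the list alone (camera adjusted p = 6.23e-11, adjusted p = 0.854 with an estimated correlation). Of 14164 genes 4 passed, with 1224 at an unadjusted p under 0.05: Fosb, the gene model Gm45159 (1.07), Hbb-bs and Hba-a2. The simulation of this contrast called 55 unchanged genes. The 2 haemoglobin genes were near 0 in the middle-aged libraries, where all haemoglobin genes summed to 0.227 CPM in MAL and 0.024 CPM in MIF against 14.1 CPM in OAL and 29.1 CPM in OIF. Interferon (20 of 27 members, 0.0239) and cholesterol synthesis (17 of 21, 0.0381) were lower in old mice by their camera adjusted p, the unfolded protein response (19 of 24, 0.0381) was higher and acinar enzymes (0.000107) were lower, and each had an adjusted p = 0.854 with an estimated correlation. The mitochondrial share of β-like UMIs was also higher in the old libraries, with 6.19% in OAL and 6.13% in OIF against 4.90% in MAL and 4.69% in MIF. DESeq2 called 29 genes, relative log expression factors 7, and 192 passed with no low-count filter.

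Between the long and the short schedule in young mice, genes of proliferation, oxidative phosphorylation and β maturity were lower in β-like cells over the long one, as lists by camera with a preset correlation and not with an estimated one (adjusted p = 0.703 each). Pdx1 fell by 0.67 on the log2 scale (edgeR adjusted p = 1.55e-12) and Hspa1a by 1.14 (edgeR adjusted p = 1.24e-31). The mitochondrial share of β-like UMIs also differed, with 3.30% in YIF and 2.96% in YAL against 2.43% in YIF_short and 2.51% in YAL_short. Proliferation was lower in 20 of 22 members (median -0.52), of which 12 fell over all genes and 14 when adjusted over the list alone (camera adjusted p = 6.26e-10, adjusted p = 0.703 with an estimated correlation). Oxidative phosphorylation was lower in 57 of 58, with 6 that fell over all genes and 0 past the edgeR threshold when adjusted over the list alone (camera adjusted p = 7.03e-06, adjusted p = 0.703 with an estimated correlation). β maturity was lower in 20 of 27 (camera adjusted p = 0.00775, adjusted p = 0.703 with an estimated correlation), and 4 members fell over all genes and 4 adjusted over the list alone, namely Pdx1, Foxa2 (-0.40), Mlxipl (-0.33) and Neurod1 (-0.25), transcription factors of endocrine cells and of glucose response.

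Of 13848 genes compared between the schedules, 992 were higher and 1075 lower over the long one in edgeR, and DESeq2 called 133, with 14 of the 20 named genes among them. With 1 residual degree of freedom, edgeR gave the prior an infinite weight here and took the spread of each gene from the trend shared across genes, so its p-values hold no spread of the gene itself. The named genes that rose were Baiap2 (0.86), a scaffold of the actin cytoskeleton, Dgkh (0.78), a diacylglycerol kinase, Nfkbiz (0.76), Trp53inp1 (0.72), Pde5a (0.70), which degrades cyclic GMP, Mirg (0.67), Sgms2 (0.64), a sphingomyelin synthase, Stk40 (0.62), Csnk2a2 (0.58) and Tead1 (0.58). Rasd1 (-0.91), Depp1 (-0.66), Jagn1 (-0.61), Gpx3 (-0.56), a secreted glutathione peroxidase, Fh1 (-0.55), the fumarase gene, H2aw (-0.54), Btg2 (-0.54) and Cd81 (-0.53) fell. Acinar enzymes (0.000267) and fasting (0.0212) were higher and immediate early genes (0.000318) lower by their camera adjusted p, with an adjusted p = 0.703 with an estimated correlation. Of the acinar enzymes 7 rose over all genes, and 11 rose and 1 fell adjusted over the list alone, and of the immediate early genes 3 rose and 9 fell over all genes, and 4 rose and 11 fell adjusted over the list alone. Duration goes with the age of the mice at the end, so the 2 cannot be told apart.

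Within the young long pair, with 1 library each and no test, Hspa1a was at 59.6 CPM in YIF and 169 CPM in YAL, and Txnip at 56.6 CPM (exact interval 54.9 to 58.3) and 140 CPM (137 to 144). Txnip was at 35.8 CPM in YIF_AL and 49.5 CPM in Ybaseline. Dbp was at 132 CPM in YIF, 69.8 CPM in YAL, 97.6 CPM in YIF_AL and 113 CPM in Ybaseline. Other high ratios in this pair, within the naming rule, were those of Fh1 (0.81), Herpud1 (0.80), S100a10 (0.76), Cox6a2 (0.64), a respiratory chain subunit, Tent5a (0.61), Dnajb9 (0.60), Mrps12 (0.52) and Sec61a1 (0.49), a subunit of the translocon. Low ratios were those of Tmsb15b2 (-1.28), Btg2 (-1.24), Jun (-1.17), Egr1 (-1.13), C2cd4b (-1.11), Dusp1 (-0.99), Atf3 (-0.98) and Junb (-0.97). In the short pair, within the naming rule and its limit of 100 CPM, Dbp (0.91), Herpud1 (0.75), Tent5a (0.71), Tmsb15b2 (0.56) and Hspa5 (0.53) were highest, and Txnip (-0.86), Btg2 (-0.68), C2cd4b (-0.65), Lpl (-0.61) and Mt2 (-0.59) lowest.

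By the same rule, within the middle-aged pair the metallothionein Mt1 (0.38), Mafa (0.38), Mt2 (0.32), Atp5md (0.30) and Tomm7 (0.27) had the highest ratios, and Mif (-0.44), Hspa8 (-0.33), Aldoa (-0.25), Nucb2 (-0.24) and Nupr1 (-0.23) the lowest. Within the old pair, by the same rule, which leaves out acinar enzymes (median 2.88 there), Sdf2l1 (0.61), a chaperone of the endoplasmic reticulum, Ubr4 (0.59), Lpl (0.55), Nucb2 (0.48) and Mif (0.47) were highest, and Nupr1 (-0.73), Mt2 (-0.40), Fos (-0.39), Egr1 (-0.38) and Mt1 (-0.37) lowest. The median log2 ratio of the β maturity list was -0.13 in the young long pair, -0.08 in the short pair, 0.14 in the middle-aged pair and 0.10 in the old pair, at the percentiles 0.02, 0.04, 100 and 98.8 of random lists matched on expression. Scaling by library totals moved the median of all genes by 0.106 in the young long pair and by -0.13 in the old pair, and turned the maturity median of the old pair to -0.035.

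Across 1353 genes of at least 50 CPM in β-like cells, the log2 ratios of IF to AL in the long and short young pairs correlated with a Pearson coefficient of 0.68. The coefficient was -0.34 between the middle-aged and the young long pair, -0.19 between the middle-aged and the young short pair, and -0.08 between the middle-aged and the old pair. The old pair had 0.05 with the young long and 0.07 with the young short pair. These 2 values were 0.10 and 0.27 over genes of at least 200 CPM, and 0.030 and 0.0073 with Spearman in place of Pearson. The pairs share no library, genes are not independent replicates, and no p-value is given.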

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

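The tests of library depth and of a clock shift in older mice were chosen only after the results they concern had been seen. The clock genes were picked after Arntl, Npas2, Dbp, Ciart and Nr1d1 had been seen.

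The simulation of the difference between young and older mice called 31 unchanged genes. The IF effect in β-like cells differed between young and older mice for 10 genes by the test of the difference itself (edgeR, adjusted p under 0.05). It was higher in young mice for Ciart (1.22, edgeR adjusted p = 0.0377), H1f4 (1.15, edgeR adjusted p = 0.0336), Chac1 (1.01, edgeR adjusted p = 0.0283), Ccdc86 (0.93, edgeR adjusted p = 0.0392) and Pycr1 (0.87, edgeR adjusted p = 0.0459). It was lower for Cxcl10 (-1.66, edgeR adjusted p = 0.00286) and Tifa (-1.03, edgeR adjusted p = 0.0266). The haemoglobin genes Hba-a2 (-4.60), Hba-a1 (-3.92) and Hbb-bs (-3.61) were also lower. Their sum was 0.227 CPM in MAL and 0.024 CPM in MIF, so these log2 values rest on very few UMIs and depend on the prior count. Hba-a1 and Hba-a2 took both signs when 1 pair was left out, and all 3 had a positive difference when each cell was assigned by its own hormones.

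In young mice 120 genes passed in β-like cells and in older mice 0 (edgeR, with 527 at an unadjusted p under 0.05 and 0 with DESeq2). Folds compressed by the other kit would leave the older effects on the side of the young ones. Over the 120 genes the median older log2 effect in the young direction was -0.0082 (bootstrap interval over genes -0.035 to 0.012). On the same side were 56 genes and on the opposite side 64. The genes are not independent, and the interval holds no spread between the 2 older pairs, whose effects correlated at -0.08. These values thus describe those 2 pairs only. Library depth would need less depth in the older libraries, but their lowest TMM-scaled total of β-like cells was 1.30 times the highest of the young libraries in the pairs, while totals before scaling overlapped. Without the long pair the young count was 3, and the 20 named genes kept their direction with log2 fold changes of -0.92 to 0.93. Kit and instrument change with age, so a property of those libraries and an effect of age both stay open, the latter untested.

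Immediate early genes were lower in IF libraries in α-like cells, a pattern that a difference in the handling of the islets may produce. It would lower them in every cell type, and in endothelial-like plus macrophage-like cells the summed list had a mean log2 ratio of -0.213 (SD 0.16 over 4 pairs). It was lower in 4 of 4 pairs, though only -0.024 in the middle-aged pair. The means were -0.38 in α-like, -0.29 in β-like and -0.32 in δ-like cells. Free islet RNA differed between libraries. Insulin made up 21.5% of macrophage-like UMIs in YAL and 11.7% in YIF, but 6.39% of endothelial-like UMIs in YAL and 10.2% in YIF. The check thus cannot tell these cells' own RNA from that of endocrine cells. Handling therefore stays a candidate explanation, and an effect of fasting on all islet cells would look alike.

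Some clock genes of opposite phase moved apart in β-like cells of young IF mice: Arntl had a log2 fold change of -1.54 (edgeR adjusted p = 0.041), Npas2 -2.35, Ciart 1.17 and Dbp 0.92. The other clock genes examined did not pass. Among them Cry1, of the phase of Arntl, went the other way (0.35), Clock had -0.12 and Nfil3 -0.16. Of the phase of Dbp, Nr1d1 had 0.15 and Per1 -0.08, with -0.21 and -0.39 in the long pair. Npas2 was at 0.067 CPM in YIF, near the floor. An index of Dbp-phase minus Arntl-phase genes was 1.47 and 1.17 in β-like and 1.09 and 1.03 in α-like cells of the long and short pairs. A shared clock shift of the whole islet may explain this, but δ-like cells had -0.606 (counting SE 0.14) in the long and 0.18 (SE 0.15) in the short pair. Endothelial-like plus macrophage-like cells had 0.55 (SE 0.26) and 0.65 (SE 0.28), to which free RNA may add. The δ-like value of the long pair lies below 0 beyond counting error but rests on 1 pair, so the question stays open. In older mice the index of β-like cells was 0.37 in the middle-aged and -0.269 in the old pair, which decides nothing on a shift there. The hour of killing is not given in the sources used here, and no biological explanation was tested.

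Other splits of the 8 paired libraries into 4 and 4 were fitted in the same way. A pair left whole drops out of the effect but stays in the spread, so 32 splits make 20 different fits, too few for a share under 0.05. In α-like cells 3 of the 20, the real one included, gave as many as the real 23, with 141 as the highest other, and in δ-like cells 8 of the 20 gave as many as the real 3, with 50 as the highest other. In β-like cells the real count is 0, which each of the 20 reaches whatever the data, with 236 as the highest other. Of the 8 splits that part every pair, the real one included, 2 in α-like and 4 in δ-like cells gave as many genes. The highest others part young IF from young AL and leave the older pairs whole. They are thus the IF contrast of the young pairs, with the older pairs in the spread.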

How the results depend on the processing

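Leaving out cells with a second hormone, and the estimated correlation, fry and left-out pairs for lists in α- and δ-like cells, were chosen only after the results had been seen, as were the left-out pairs for shares. The pairs were formed by age and duration, not by sample numbers, and are a term of the fits of IF against AL. Leaving out a pair assumes that the remaining pair of an age class varies like the others. In the fit with separate IF terms, only the disagreement of the 2 pairs of the other age class is then left as a gene's own spread. No such fit was possible for old against middle-aged and long against short, which would have no residual degrees of freedom. The cause was not tested for any change given here, except that leaving out a pair leaves fewer libraries and no filter adds genes of low count.

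Of the counts of genes, 28 stayed within 1.5 times the reported count under alternatives fixed beforehand other than left-out pairs and 17 did not, and with a pair left out, also fixed beforehand, 8 did and 16 did not. Over 4 pairs in β-like cells (0) DESeq2 gave 8, no low-count filter 13, and leaving out a pair 0 to 21. In young mice (120) these were 233, 1158, and 3 to 1318. In older mice (0) no filter gave 113, assigning single cells 11, and leaving out a pair 0 to 440. For the difference (10) DESeq2 gave 49, no filter 508, assigning single cells 53, leaving out cells with a second hormone 22, and leaving out a pair 4 to 635. In α-like cells (23) the counts were 10, 147, and 12 to 43. In δ-like cells (3) DESeq2 gave 0, no filter 56, leaving out cells with a second hormone 16, and leaving out a pair 1 to 21. Old against middle-aged (4) had 29 with DESeq2, 7 with relative log expression factors and 192 with no filter. Long against short (2067) had 133 with DESeq2. Of the 120 young genes, 108 were among those of DESeq2, 112 among those with single cells assigned and 93 among those after thinning. The 20 genes named in young mice kept their direction under every alternative run; 19 passed with DESeq2, 18 with doublets kept, 18 with the stricter cell filter, 15 without the short pair and 0 without the long pair.

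Of the lists in β-like cells, those called were 8 over 4 pairs, 7 in young mice, 10 in older mice, 9 for the difference, 5 for old against middle-aged and 6 for long against short. With an estimated correlation, and with fry, 0 were called in each of the 6 contrasts. These fits have 1 to 3 residual degrees of freedom, so the estimated correlation leaves little power and decides nothing on a single list. The preset correlation counts members of a list as nearly independent, so its p-values may be too small. Immediate early genes in α- and δ-like cells passed with an estimated correlation and with fry (fry adjusted p = 0.0210 in α-like and 0.0196 in δ-like cells). Lists that turned direction when a pair was left out, with the range of their camera adjusted p, were in young mice α identity (0.690 to 0.850), autophagy (0.116 to 0.726), genes disallowed in β cells (0.438 to 0.997, and 0.881 with hormone genes left out), exocytosis (0.264 to 0.982), glycolysis (0.599 to 0.997, and 0.915 with fry) and oxidative phosphorylation (0.0462 to 0.637). In older mice they were acinar enzymes (6.37e-188 to 8.23e-07, turned at 6.01e-35 without the middle-aged pair), autophagy (0.0376 to 0.994), cholesterol synthesis (3.61e-33 to 0.994) and the unfolded protein response (1.93e-10 to 0.0825). For the difference it was cholesterol synthesis (9.20e-15 to 0.609).

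Of the named genes, 468 values under alternatives fixed beforehand other than left-out pairs kept their direction and side of the threshold, 28 lost and 6 gained the threshold, and 3 turned. With a pair left out these were 183, 53, 8 and 8. Leaving out a pair gave log2 values in young mice of -0.22 to 0.016 for Ins1, -0.11 to 0.014 for Ucn3 and -0.24 to 0.068 for Slc2a2. In older mice they were -0.024 to 0.185 for Iapp, -0.151 to 0.553 for Slc2a2 and -0.160 to 0.097 for Slc30a8. For the difference they were -4.11 to 0.42 for Hba-a1 and -4.80 to 0.045 for Hba-a2, and with single cells assigned 4.04 for Hba-a1, 4.04 for Hba-a2 and 5.22 for Hbb-bs.

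Mean differences in log odds of shares, IF minus AL, ranged with a pair left out from -0.148 to 0.271 for β-like and -0.278 to 0.172 for α-like cells. They ranged from -0.129 to 0.262 for δ-like and -0.00052 to 0.161 for macrophage-like cells. With single cells assigned, β-like cells had 0.042 and δ-like cells 0.295. The 196 values of single-pair genes under other settings kept their direction, as did the 12 planned and 6 added values of correlations, though those of the old with the young pairs varied in size. Values of genes of low level rest on few UMIs, such as those of the haemoglobin genes in MAL (0.227 CPM in sum) and MIF (0.024 CPM).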

Other observations

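No test was run on the values in this part, which were picked after they had been seen. In β-like cells of young mice the proliferation list, with genes of DNA replication and mitosis, was lower at the end of the long schedule than in Ybaseline, with a median log2 ratio of -1.41 for YAL and -1.16 for YIF. It was 0.92 higher in YIF than in YIF_AL and 0.58 higher in YIF_short than in YAL_short, with 21 of 22 members higher in each, but only 0.096 higher in YIF than in YAL, with 15 of 22 higher. A cluster of proliferating cells led by Pbk, Ube2c and Top2a is part of these sums and held 2.02% of the β-like cells in Ybaseline, 0.92% in YIF, 0.776% in YAL, 0.149% in YIF_AL (4 cells), 1.11% in YIF_short and 0.616% in YAL_short, the same order as the list values compared here. These are single libraries.

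Of the β-like cells of YIF_AL, 68.5% lay in 1 cluster, and a cluster that holds most of 1 library can be that library rather than a kind of cell. Against YAL, its median log2 ratio was -1.10 for immediate early genes (21 of 22 lower), 0.49 for the integrated stress response (17 of 20 higher) and -0.22 for β maturity (24 of 27 lower). YIF against YAL had medians of -0.86, 0.50 and -0.13 on these lists, on the same side as YIF_AL. Both comparisons share the library YAL, so their sides are not independent. Interferon and antigen presentation was 0.36 against YAL, and YIF was at -0.51 against YIF_AL on that list. Pdx1 was at 27.4 CPM in YIF_AL, 36.1 CPM in YIF, 51.3 CPM in YAL and 48.4 CPM in Ybaseline, and Herpud1 at 267 CPM, 456 CPM, 263 CPM and 361 CPM.

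Nupr1, a chromatin protein induced by stress, was at 16.6 CPM in β-like cells of YIF_AL and 13.2 CPM in Ybaseline, and at 825 CPM in MAL, 704 CPM in MIF, 804 CPM in OAL and 484 CPM in OIF. Kit and age class change together between these libraries.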
